A study of Mus musculus with 6 samples.

How the data were processed

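Right-lobe liver RNA was measured in 6 samples on single-colour Agilent arrays, 3 after ligation of the left portal vein branch (PVBL) and 3 after sham surgery, and the groups and replicate numbers came from the labels' source names. Per the labels' protocols, total RNA was isolated with a column kit and labelled with Cy3 by the low-input amplification kit. The deposited scanner files give intensity values per spot, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1 on an array of design 028005 annotated on mouse build mm9. The submitters' processing notes name Agilent Feature Extraction 9.1, which differs from the version in the file headers, and the header was taken as the record of these files. Per the file headers, the processed signal was already corrected for background by the scanner software. The deposited value table of the series holds log2 values, for which no normalization is given in the sources used here.

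That table was set against the scanner files. Its log2 values matched the log2 intensities scaled to the 75th percentile and centred on each probe's median over the 6 arrays, with r of at least 0.9997 per array over the shared probes, so its direction is settled and its level is lost by the centring. The medians of its columns were -0.18, -0.15 and -0.22 for PVBL 1 to 3 and 0.17, 0.15 and 0.18 for sham 1 to 3. The table held 7850 rows, 1 of them a control. In 100% of its rows the PVBL and sham values did not overlap, against 30.6% of all probes on the arrays and 10% expected by chance, so its rows had been chosen on the difference between the groups. It was used only as an alternative. Because of that choice 4403 of its 4524 genes were called, so calls made with it were largely fixed in advance.

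For the main values, log2 of the processed signal was taken, spots marked as outliers (115 to 201 per array) and 3671 control spots were left out, spots of a probe were averaged, and each array's 75th percentile over all probes was subtracted. Log2 levels are therefore relative to that percentile, and the precision is limited by the number of arrays. Probes were tested if they were well above background on all arrays of at least 1 group, which left 27918 of 55681. Genes were named by matching the probe's RefSeq accession, without versions, to the transcripts of a RefSeq gene table (assembly GRCm38.p6), used for names only because the arrays use another build. Symbols were found for 26413 probes (47.4%), 0 of them with several symbols, and 29268 probes remained unnamed and were tested apart. No coordinates are given for named genes for this reason. Of the probes passing the filter 17529 had a symbol. They stood for 13586 genes, and the probe with the highest mean stood for a gene with several. Of 3321 genes with more than 1 tested probe, 22 had probes called in opposite directions when each was tested alone. Of 1038 called genes with more than 1 probe, all probes were called the same way in 608.

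Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient for the group and eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. SE values are limma's moderated standard errors, and SD values are over the 3 arrays of a group. A gene that was not well above background on any array of a group has only a bound there. The fold is then given as at least the mean of the bright group over the mean, per array of the dim group, of the higher of the gene's own signal and the lowest signal that was well above background on that array. Before the data were examined, 39 gene lists were fixed: cell cycle, metabolism, stress, signalling and the markers of cell types and neighbouring tissues. Each was tested with camera (preset correlation 0.01, at least 5 members, Benjamini-Hochberg over the 39 lists), beside the count of called members over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list's genes move on balance 1 way, and past its threshold were 13 lists, or 37 when changes in either direction were counted. Neither version compares a list with other genes. Some genes stand in more than 1 list, such as C8b among plasma proteins and male-biased genes, so the list results are not independent.

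The genes named in the text were chosen by a rule written before the data were examined. It took the 10 largest rises and falls among called genes measured on all 6 arrays, up to 5 genes per direction above background in 1 group only, up to 4 called members of each list with the largest change (or the 2 brightest if none was called), and 16 genes whatever their values. Genes named after their values were seen are marked as such, and 1 gene that the rule takes is not reported here. Genes with near-identical copies (Mup, Cyp2c, Cyp3a, Cyp4a, Saa, haemoglobin and Ugt1a families) are uncertain between members, and the same holds for Kifc5b and for the hepcidin pair.

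The steps were tested on simulated data with the arrays' own means and spreads. In the simulated comparison of PVBL with sham over 13569 genes, 200 genes were changed. Of 50 genes changed 1.5-fold 18% were recovered, of 50 changed 2-fold 52%, of 50 changed 4-fold 84% and of 50 changed 16-fold 100%, with 5.93% false calls among all calls. Far fewer genes were changed there than the 32.9% called in the real comparison, so these shares do not carry over to it. An alternative was counted as a change of direction only where the result was called in at least 1 of the settings compared. The replicate numbers were checked as possible pairs. The alternatives were another background correction (normexp with an offset of 50), quantile normalization, median scaling, another set of probes for the percentile, the authors' value table, other filters on dim probes, the mean over a gene's probes, single probes, a floor, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array, and an ordinary test without moderation. Normexp had been planned on mean signals and was run on the median signals that the files hold. The array weights were 5.51, 0.41 and 0.28 for PVBL 1 to 3, so calls with them rest mostly on PVBL 1 in that group. Scaling on 8 spike-in probes, which match RNA added at labelling, and a fit without PVBL 3 and sham 3 were added after the data were examined. A slide or scan block was not run because all arrays share 1 slide and 1 scan.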

Results

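Gene expression was measured in the livers of male C57BL/6J mice 3 days after surgery on the portal vein. In the PVBL group the left branch of the portal vein, the vessel that carries blood from the gut to the liver, had been ligated, and the right lobe, whose portal branch was left open, was taken as regenerating liver. The sham group had a sham operation. Each group had 3 samples, each on its own array, giving 6 single-colour (Cy3) Agilent arrays in all. The labels number the samples within a group and do not say that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value.

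Each array held 55681 probes that were not controls. Between 48.1% and 53.6% of them were well above background on an array. The signal at the 75th percentile was 407, 331 and 340 units on the PVBL arrays and 315, 301 and 203 units on the sham arrays, and no spot was saturated. After scaling and filtering, 13586 genes were tested. Arrays of the same group correlated over these genes with r from 0.982 to 0.992 within PVBL and from 0.991 to 0.996 within sham, against 0.948 to 0.960 between groups (genes are not independent replicates). The first principal component held 75% of the variance and separated the groups. The second held 11.9% and set PVBL 3 apart from PVBL 1 and PVBL 2. All arrays lay on 1 slide with 1 scan. The sham arrays were in row 1 of the slide and the PVBL arrays in row 2, so slide row and surgery cannot be told apart.

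The comparison asked how the transcripts of the right lobe, left with the portal flow, differed from those of sham-operated liver at 3 days. Cell division genes rose by the largest amounts. Transcripts of Cdc20, which activates the anaphase-promoting complex, were 148-fold higher in PVBL (log2 difference 7.21 ± 0.25, SE, n = 3 per group) and 70.4-fold higher with normexp background correction. Mki67, a marker of proliferating cells, was 66.8-fold higher (32.0-fold with normexp), and Ccnd1, a cyclin of the G1 phase, 7.47-fold higher. The falls were smaller and held many genes of hepatocyte metabolism. Hamp2, a hepcidin gene, was 31.9-fold lower, and Hsd3b5, a steroid dehydrogenase of male liver, 11.3-fold lower. The call of Hsd3b5 was lost without any 1 of the sham arrays (log2 differences from -3.69 to -3.22), and its fold was 4.64 without PVBL replicate 3. Albumin transcripts (Alb) showed no change past the threshold (log2 difference -0.28 ± 0.15, adjusted p = 0.191), nor did Hnf4a, a hepatocyte transcription factor gene (-0.17 ± 0.14, adjusted p = 0.383), and both values were above 0 with quantile and spike-in scaling, while Alb was called lower with array weights (-0.31).

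In limma with Benjamini-Hochberg adjustment, 4475 genes (32.9% of those tested) passed the adjusted p threshold of 0.05. Of these, 2053 were higher and 2422 lower in PVBL, and 1556 differed at least 2-fold, 931 upward and 625 downward. At least 16-fold changes were seen for 129 genes upward and 2 downward. These fold counts use the fitted difference, also for genes below background in a group, whose fold is only a bound. Among genes well above background on all arrays, only Hamp2 fell at least 16-fold, and the next largest fall was that of Bmf at 14.3-fold. The split between rises and falls depended on the scaling. It was 2639 higher and 1559 lower when arrays were scaled on their median. It was 1484 higher and 171 lower when they were scaled on spike-in probes, an alternative chosen after the data were examined. The median over all genes tested was -0.10 with the 75th percentile and 0.33 with spike-in scaling, and falls are therefore relative to the bulk of the genes. Without sham replicate 1 the count of changed genes was 2391 (1322 higher, 1069 lower), and without sham replicate 2 it was 2839. The count of lower genes was 1428 without sham replicate 2, 1513 without sham replicate 3 and 1594 without PVBL replicate 1.

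**Figure D1:**
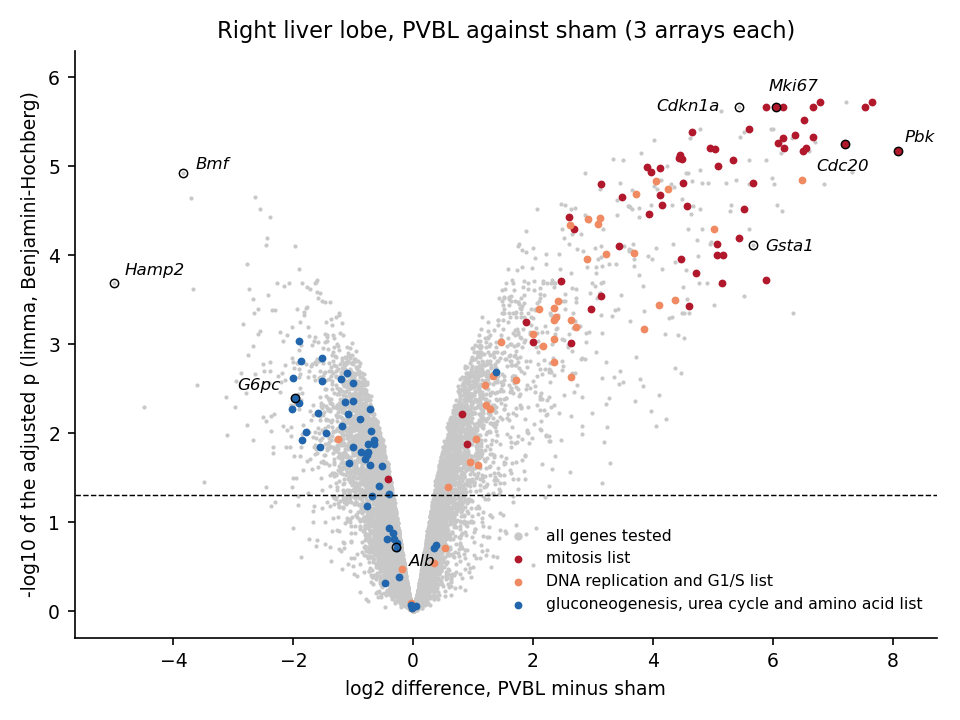
Each point is 1 of the 13586 genes tested, with the log2 difference between PVBL and sham (n = 3 arrays each) on the horizontal axis and minus log10 of limma's adjusted p on the vertical axis, the dashed line marking an adjusted p of 0.05. Members of the mitosis list (dark red) lie between -0.43 and 8.09, genes below background in sham being drawn at their fitted difference, and Hamp2 lies at -5.00.

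Among genes well above background on all 6 arrays, the 10 largest rises were in Cdc20, Cdkn3, Prc1, Ly6d, Cdca3, Birc5, Aurka, Ccna2, Ube2c and Mki67. They ranged from 66.8-fold to 148-fold, and all but Ly6d, a membrane protein, are known from cell division. Birc5 (survivin) was 83.2-fold and Ccna2 (cyclin A2) 72.0-fold higher. Pbk, Kifc5b, Tpx2, Diaph3 and Aspm were well above background on all 3 PVBL arrays and on no sham array, at least 66.2-fold, 52.2-fold, 48.4-fold, 47.8-fold and 44.3-fold higher. These bounds set the PVBL mean against the lowest signal that counts as well above background, and hold for the scanner's processed signal. Normexp added an offset of 50 units to every signal, more than the lowest signals well above background (11.9 to 23.8 units). The offset makes folds of dim genes smaller by construction, so normexp values here and later do not tell how large those changes are. With normexp background correction Pbk, Kifc5b, Tpx2, Diaph3 and Aspm differed by 3.82, 3.57, 3.44, 3.03 and 3.24 on the log2 scale, all 15 named genes with a bound lay below it, and 30 of the other 152 named genes with a call had a fold over 1.5 times smaller, Cdc20 being 70.4-fold, Cdca3 52.7-fold, Ly6d 59.4-fold, Mki67 32.0-fold, Prc1 and Cdkn3 each 27.9-fold, Ube2c 24.7-fold, Aurka 24.0-fold and Ccna2 23.7-fold higher. Tpx2 had another probe that was not called, and with any 1 PVBL array left out that probe stood for the gene and the call was lost (0.66, 0.58 and 1.31 without PVBL 1, PVBL 2 and PVBL 3). Of the 59 measured genes of the mitosis list, 58 rose and 1 fell (the same 59 adjusted over the list alone), with a median log2 difference of 4.95, or 4.16 with 22 members at their bound and 2.90 with normexp. Plk1, a mitotic kinase, had a log2 difference of 7.66 ± 0.16 and was above background on 1 of the 3 sham arrays, the difference being 5.30 with normexp. The list shifted upward in camera (adjusted p = 3.19e-49). It did not pass with an estimated correlation (adjusted p = 0.264).

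Genes of DNA replication and the G1/S transition rose in 37 of 43 cases, fell in 1 and missed the threshold in 5, and 38 were called adjusted over the list alone. Uhrf1, which maintains DNA methylation at replication, was 89.8-fold higher, with 2 of the 3 sham arrays above background, but 10.3-fold in its other probe and 17.9-fold with normexp. The replicative helicase gene Mcm5 was 32.3-fold higher (17.3-fold with normexp), and Mcm6 rose by 4.25 ± 0.20 on the log2 scale. Pole2, a subunit of DNA polymerase epsilon, was at least 11.7-fold higher (log2 difference 1.64 with normexp). The median was 2.35, or 1.91 with normexp (camera adjusted p = 4.65e-21; adjusted p = 0.781 with an estimated correlation). The exceptions in these lists, named here after their values were seen, were Mcm10 (fell by 1.25, adjusted p = 0.0116) and Pttg1 (fell by 0.43, adjusted p = 0.0328, in 1 of its 2 probes). Of 33 genes of nucleotide and one-carbon synthesis, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.50. Psat1, of serine synthesis, was 11.5-fold, the mitochondrial folate enzyme gene Mthfd1l 8.18-fold and Ctps (CTP synthase) 3.96-fold higher, and Mthfd2 was at least 7.64-fold higher, but 1.87-fold with normexp, where Psat1 was 4.78-fold and Mthfd1l 3.66-fold higher. Of 42 genes of ribosome biogenesis 17 rose and none fell (18 adjusted over the list alone), with a median of 0.45. Nop58, of small nucleolar ribonucleoproteins, was 2.72-fold higher, and Rrp12, Nolc1 and Gar1 were 2.31-fold, 2.13-fold and 2.12-fold higher, Rrp12 1.42-fold with normexp. Both lists shifted upward in camera (adjusted p = 0.000115 and 7.68e-07), and both had adjusted p = 0.781 with an estimated correlation.

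Some genes of CDK inhibitors and p53 targets rose as well. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was 43.5-fold higher (log2 level 2.29 ± 0.11 in PVBL and -3.15 ± 0.15 in sham, SD, n = 3), a log2 difference of 5.44, against 2.38 in its other probe and 3.89 with normexp. The p53 targets Tnfrsf10b, a death receptor gene above background on 2 of the 3 sham arrays, Phlda3 and Aen were 18.9-fold (4.86-fold with normexp), 12.6-fold and 2.86-fold higher. Of 25 genes in the list of CDK inhibitors and p53 targets, 13 rose and 1 fell, the same counts adjusted over the list alone. The latter was Cdkn1c, another CDK inhibitor, named after its value was seen (-0.80 ± 0.15). The median was 0.79, or 0.42 with normexp (camera adjusted p = 0.000110; adjusted p = 0.264 with an estimated correlation). Of 19 immediate early genes 8 rose and none fell, also adjusted over the list alone, with Atf3 at 7.02-fold, Egr1 at 4.79-fold, Fos at 4.72-fold (above background on 2 of the 3 sham arrays) and Jun at 4.13-fold. Without sham replicate 2 Atf3 rose by 3.42 on the log2 scale, and with normexp it was 4.18-fold and Fos 1.58-fold higher. Their median of 0.45 was past the threshold in camera (adjusted p = 0.0398; adjusted p = 0.781 with an estimated correlation), and the call was lost without PVBL replicate 2 (median 0.65), PVBL replicate 3 (0.14) or sham replicate 3 (0.44), with adjusted p = 0.0548, 0.0871 and 0.0647, and with normexp (0.30). Without sham replicate 2 the median was 0.29.

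Growth factor genes moved both ways. Of 48 genes of growth factors, cytokines and receptors 10 rose and 13 fell (10 and 16 adjusted over the list alone), and no shift of the list was called (median -0.25, above 0 with spike-in scaling; camera adjusted p = 0.588). Gdf15 and the TWEAK receptor gene Tnfrsf12a were 8.84-fold and 8.82-fold higher and Pdgfa 3.54-fold higher, while Igfbp3, a carrier of insulin-like growth factors measured on 2 of the 3 PVBL arrays, was 5.33-fold lower (2.72-fold with normexp). Hgf, the hepatocyte growth factor gene, rose by 0.77 ± 0.23 on the log2 scale (adjusted p = 0.0403) and its receptor gene Met fell by 0.57 (adjusted p = 0.0447). The call of Hgf was lost under 7 and that of Met under 12 of the alternative settings, with Hgf at 0.55 to 0.87 without PVBL 1, PVBL 3, sham 1 or sham 2, and Met at -0.65 to -0.40 without any 1 array. Il6 (-0.04 ± 0.39, adjusted p = 0.938), Igf1 (-0.41 ± 0.19, adjusted p = 0.134), Igfbp1 (-0.11 ± 0.33, adjusted p = 0.822) and Egfr (-0.50 ± 0.40, adjusted p = 0.357) did not pass the threshold. The first 3 of these were above 0 with spike-in scaling, Il6 and Igfbp1 also with quantile and median scaling. For Igf1, 2 of 4 probes and for Egfr, 2 of 3 probes were called lower on their own, so the probes of these genes differed. Igf1 was called lower in the authors' table (-1.11), with the mean over its probes (-0.71) and with array weights (-0.32), and Egfr in the authors' table (-1.15). Rows of that table were chosen on the group difference and 4403 of its 4524 genes were called, so calls there are no separate evidence. Without PVBL 3 Egfr was at -0.014 and without PVBL 2 at -0.76. Il6 was above 0 without PVBL 1, PVBL 2 or sham 1 (0.13 to 0.27), and Igfbp1 without PVBL 2 or sham 1 (0.20 and 0.043).

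Several lists of hepatocyte genes fell relative to the other genes. Of 52 genes of gluconeogenesis, the urea cycle and amino acid breakdown 36 fell and 1 rose (38 and 1 adjusted over the list alone), with a median of -0.77. The glucose-6-phosphatase gene G6pc was 3.91-fold lower, Sds, serine dehydratase, 4.04-fold lower, Csad, of taurine synthesis, 4.03-fold lower and the methyltransferase gene Gnmt 3.76-fold lower. The member that rose was Acmsd (log2 difference 1.38 ± 0.18), named after its value was seen. Of 47 genes of plasma proteins and clotting 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median of -0.44. Hrg and the complement genes C8g and C8b were 2.10-fold, 2.07-fold and 1.88-fold lower, and Apoa4, an apolipoprotein gene, 2.65-fold higher. The call of Hrg was lost without sham 1 or sham 2 (-0.94 and -1.03), that of C8b without sham 1 or sham 3 (-0.92 and -0.80) and that of Apoa4 without PVBL 1 or any 1 sham array (1.26 to 1.53). Among 27 periportal markers 17 fell and 4 rose (19 and 6 adjusted over the list alone), with a median of -0.70. Many of these markers, among them G6pc, Sds and Gls2, also stand in the gluconeogenesis, urea cycle and amino acid list, so the falls of these lists are not separate results. Gls2, liver glutaminase, was 3.76-fold lower, and Spp1, osteopontin, which biliary cells also make, was 5.51-fold higher. These lists shifted downward in camera (adjusted p = 1.66e-08, 7.81e-05 and 0.0184), and each had adjusted p = 0.781 with an estimated correlation. With spike-in scaling their medians were -0.34, -0.02 and -0.27, and the plasma protein list lost its call with quantile scaling (-0.062). In the same PVBL arrays the stellate cell and biliary marker lists were shifted upward, with medians of 0.72 and 0.82 (0.44 and 0.46 with normexp; adjusted p = 0.781 for both with an estimated correlation). Of 27 pericentral markers 4 fell and none rose (1 adjusted over the list alone), among them Glul, glutamine synthetase, 2.07-fold lower, Cyp2e1 2.10-fold lower and Cyp27a1 1.87-fold lower. The calls of Glul and Cyp2e1 were lost without any 1 of the sham arrays (-1.10 to -0.98 and -1.13 to -0.95). The list missed the threshold (median -0.40, but 0.02 with spike-in scaling; adjusted p = 0.0576) and passed it without PVBL replicate 1, PVBL replicate 2 or sham replicate 2 (medians -0.48, -0.48 and -0.52).

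Genes known to be higher in male than in female liver fell in 16 of 27 cases and rose in none (18 and none adjusted over the list alone). Hsd3b5 was 11.3-fold, Elovl3, a fatty acid elongase gene, 5.18-fold and the transporter gene Slco1a1 4.15-fold lower. Mup21 was 4.11-fold lower, but its probe may meet other members of the near-identical Mup family. The median was -0.75, or -0.49 with quantile and -0.33 with spike-in scaling (camera adjusted p = 7.81e-05; adjusted p = 0.781 with an estimated correlation). The spread between PVBL arrays was wide for Hsd3b5 (log2 level 3.88 ± 2.24, against 7.38 ± 0.50 in sham, SD, n = 3), and its log2 difference was -2.21 without PVBL 3 and -4.26 without PVBL 2. The call of Hsd3b5 was lost without any 1 sham array (-3.69 to -3.22) and that of Slco1a1 without sham 3 (-1.94). No shift was called for genes known to be higher in female liver (camera adjusted p = 0.712), with 3 of 24 higher and 4 lower, the same adjusted over the list alone. Their median was -0.01 (above 0 with normexp and every other scaling, and at 0.054, 0.12 and 0.020 without PVBL 3, sham 1 and sham 2) and their mean 0.12, with Prom1 at 7.90-fold higher and Lifr, Vldlr and Gna14 at 2.80-fold, 2.78-fold and 2.75-fold lower. For Lifr 2 of 3 probes were called. The call of Lifr was lost without sham 1 or sham 3 (-1.53 and -1.15) and that of Vldlr without sham 1 (-1.30).

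Of 35 cytochrome P450 genes of drug metabolism 10 fell and 2 rose (14 and 2 adjusted over the list alone). Cyp2j5, Cyp2d40 and Cyp2j9 were 3.13-fold, 2.49-fold and 2.32-fold lower, the call of Cyp2d40 being lost without PVBL 1, sham 1 or sham 3 (-1.32, -1.32 and -1.22). Cyp2c55, uncertain because members of its family are near-identical, was 6.95-fold higher. The median of -0.47 (-0.27 with quantile and -0.04 with spike-in scaling) was just past the threshold in camera (adjusted p = 0.0485; adjusted p = 0.795 with an estimated correlation) and the call was lost without PVBL replicate 3 (median -0.28, adjusted p = 0.0871), sham replicate 1 or sham replicate 3 (-0.46 and -0.51, adjusted p = 0.0709 and 0.106). In contrast, genes of conjugating and antioxidant enzymes split, with 12 of 42 higher and 9 lower (12 and 10 adjusted over the list alone). Their median was -0.02 (above 0 with quantile, median, spike-in and the other percentile scaling, and at 0.0050 and 0.011 without PVBL 1 and sham 2), their mean 0.38 and camera's adjusted p 0.308. The glutathione transferase genes Gsta1 and Gstm3 were 51.1-fold and 12.9-fold higher, the latter in both of its probes. Srxn1, sulfiredoxin, was 6.34-fold and Nqo1, a quinone reductase gene, 6.31-fold higher.

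**Figure D2:**
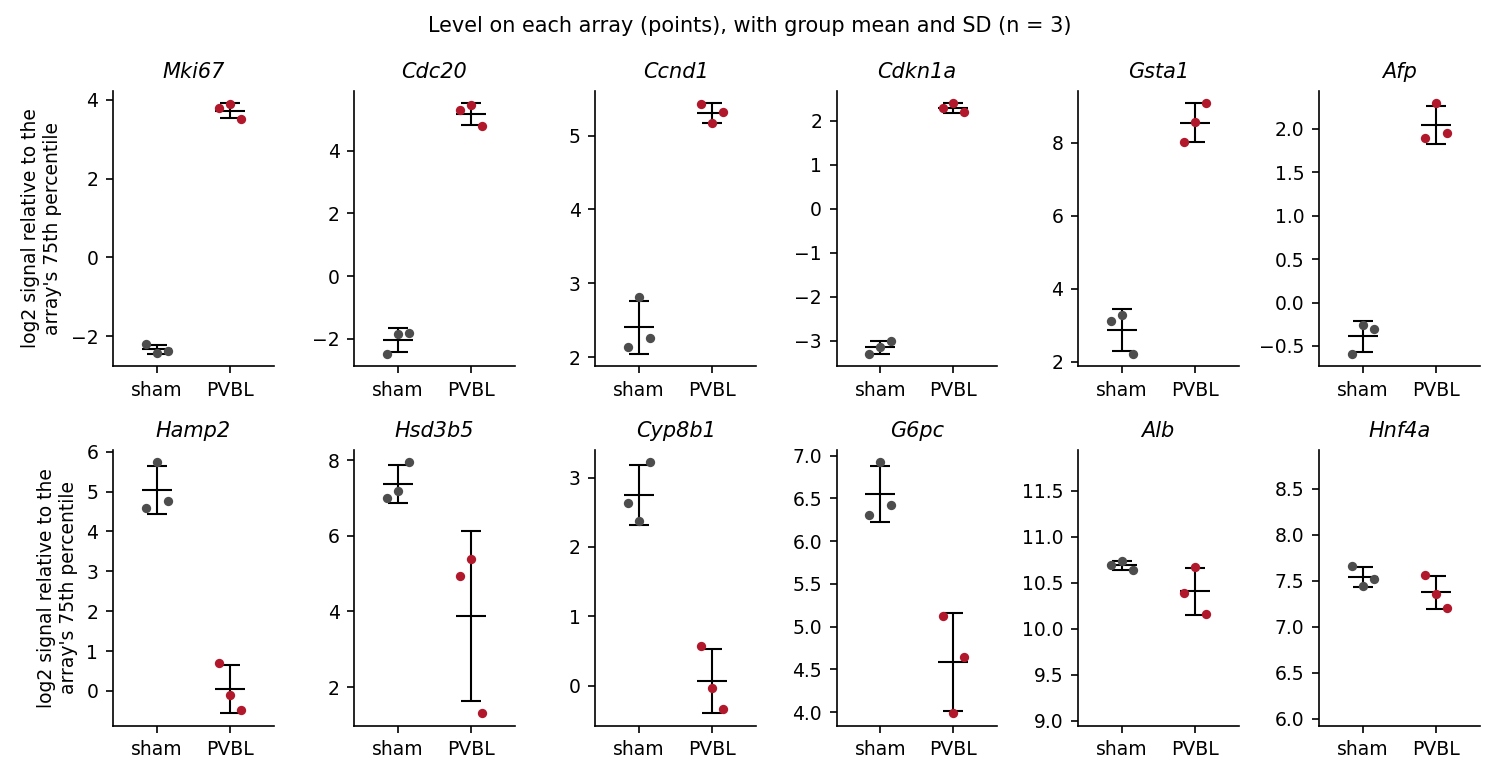
Log2 signal of 12 genes relative to the array's 75th percentile, on each of 3 sham (grey) and 3 PVBL (red) arrays, with the group mean and SD as bars. Mki67 moves from -2.33 in sham to 3.73 in PVBL and Hamp2 from 5.04 to 0.04, while Alb is at 10.69 in sham and 10.41 in PVBL, a difference that did not pass the test and turned its sign with quantile and spike-in scaling.

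Lipid and bile acid genes moved in both directions. Of 28 genes of bile acid synthesis and transport 4 rose and 11 fell, also adjusted over the list alone, and no shift of the list was called (median -0.35, above 0 with spike-in scaling; camera adjusted p = 0.171). Cyp8b1, which directs synthesis to cholic acid, fell by 2.68 ± 0.29 on the log2 scale, Cyp7b1 was 3.39-fold lower, and Slc51b, a bile acid exporter subunit, 7.02-fold higher. The call of Cyp7b1 was lost without PVBL 1, PVBL 3, sham 1 or sham 3 (-1.83 to -1.28). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.24 ± 0.41 (adjusted p = 0.668), by -0.15 without PVBL 1 and by 0.73 without PVBL 3. It was called higher with array weights (0.93), a fit in which PVBL 1 had a weight of 5.51 against 0.41 and 0.28 for PVBL 2 and PVBL 3. Of 45 genes of fatty acid oxidation and PPAR-alpha 10 rose and 12 fell (10 and 14 adjusted over the list alone), with a median of -0.29 (above 0 with spike-in scaling), a mean of 0.07 and a camera adjusted p of 0.457. The lipid droplet gene Cidea was at least 8.06-fold higher (1.96-fold with normexp), Cidec 4.56-fold higher, Pdk4, a brake on pyruvate oxidation, was 3.63-fold and Acot2 3.38-fold higher (1.94-fold with normexp). The call of Pdk4 was lost without sham 1 or sham 2 (1.72 and 1.87). Of 22 genes of fatty acid synthesis 5 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.29, above 0 with spike-in scaling, camera adjusted p = 0.457). Acacb, Srebf1, Thrsp and Dgat2 were 2.50-fold, 2.43-fold, 2.23-fold and 2.00-fold lower. The call of Acacb was lost without PVBL 1 or sham 1 (-1.24 and -1.26) and that of Thrsp without any 1 array but sham 3 (-1.29 to -0.73). No shift was called for cholesterol synthesis genes (2 of 25 higher, 4 lower, also adjusted over the list alone; median 0.08, but -0.048 without sham replicate 3; camera adjusted p = 0.547), with Insig1 and Stard4 1.84-fold and 1.64-fold lower and Cyp51 1.58-fold higher, and Tm7sf2 fell by 0.59 on the log2 scale. The call of Stard4 was lost without PVBL 2, PVBL 3, sham 1 or sham 2 (-0.69 to -0.60) and that of Cyp51 without PVBL 2 or any 1 sham array (0.54 to 0.73). For glycolysis and the pentose phosphate path 4 of 24 genes rose and 2 fell (3 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.0675, and 0.0450 without sham replicate 2 at a median of 0.21). Pgd and Tkt, of the pentose phosphate path, were 3.36-fold and 1.58-fold higher and Aldoc 1.59-fold lower. The call of Tkt was lost without sham 1 or sham 3 (0.69 and 0.54) and that of Aldoc without any 1 array but sham 3 (-0.71 to -0.54).

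No list of regulators or stress genes below passed the threshold in camera with the main settings. Of 29 hepatocyte transcription factor genes 9 fell and none rose, also adjusted over the list alone. Nr2f2, Cebpa, Tbx3 and Stat5b were 2.14-fold, 2.04-fold, 1.93-fold and 1.72-fold lower, and the list missed the threshold (median -0.35, above 0 with spike-in scaling; camera adjusted p = 0.0575) and passed it under 7 other settings, among them median scaling (-0.22) and trended eBayes (-0.35), and without PVBL replicate 1 or sham replicate 2 (medians -0.52 and -0.45). The call of Tbx3 was lost without PVBL 2 or any 1 sham array (-1.07 to -0.83). Among 20 circadian clock genes 6 fell and 1 rose, also adjusted over the list alone (median -0.48, but -0.054 with spike-in scaling; camera adjusted p = 0.260), with Bhlhe41 at least 2.12-fold and Cry2 and Dbp 2.03-fold and 1.71-fold lower, Dbp in 1 of its 2 probes. The call of Bhlhe41 was lost without any 1 sham array and that of Dbp without sham 1 or sham 2 (-0.78 and -0.65). No shift was called for acute phase genes (2 of 29 higher, 9 lower; 3 and 9 adjusted over the list alone; median -0.43, but -0.0037 with spike-in scaling; camera adjusted p = 0.133), except without sham replicate 3 (median -0.53, adjusted p = 0.0411). Lcn2, lipocalin, was 7.07-fold higher, the hepcidin genes Hamp2 and Hamp, which are near-identical and may share probes, 31.9-fold and 4.52-fold lower, and Mt1, metallothionein, 2.22-fold lower. Without sham 3 Lcn2 was 4.42-fold higher, and the call of Mt1 was lost without PVBL 1, PVBL 3, sham 1 or sham 2 (-1.17 to -0.88). In the hypoxia list 1 of 17 genes rose and 4 fell, also adjusted over the list alone (median -0.11, above 0 with median and spike-in scaling and at 0.0031 without PVBL replicate 2; camera adjusted p = 0.442), with Bnip3, Pdk1 and Vegfa 2.79-fold, 2.68-fold and 2.08-fold lower and P4ha2 1.79-fold higher. Genes of endoplasmic reticulum stress (1 of 24 higher, 3 lower; 1 and 2 adjusted over the list alone; median -0.18, above 0 with spike-in scaling; camera adjusted p = 0.386) included Dnajb11 and Trib3, 2.93-fold and 2.17-fold lower, and Dnajb9, 1.69-fold higher. Interferon response genes (2 of 28 higher, 6 lower, also adjusted over the list alone; median -0.26, above 0 with spike-in scaling; camera adjusted p = 0.138) included Oasl1, 2.28-fold higher, and Cd274 (measured on 2 of the 3 PVBL arrays), Ifit3 and Ifit1, 2.36-fold (1.52-fold with normexp), 1.82-fold and 1.76-fold lower. The call of Ifit3 was lost without PVBL 1, PVBL 2, sham 2 or sham 3 (-0.85 to -0.70). Without PVBL replicate 3 the interferon list passed the threshold (median -0.36, adjusted p = 0.0380).

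Markers of other liver cell types moved apart. Of 37 stellate cell and fibroblast markers 16 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.72, or 0.44 with normexp (camera adjusted p = 0.000108; adjusted p = 0.781 with an estimated correlation and 0.0581 with the authors' table). Timp1, an inhibitor of metalloproteases above background on 2 of the 3 sham arrays, was 14.3-fold, collagen gene Col1a1 4.64-fold, Fbln2 3.43-fold and the smooth muscle actin gene Acta2 3.36-fold higher. Timp1 was 9.52-fold higher without PVBL 3 and 5.14-fold with normexp. Of 19 biliary and progenitor markers 9 rose and 1 fell, also adjusted over the list alone, with a median of 0.82, or 0.46 with normexp (camera adjusted p = 0.00123; adjusted p = 0.781 with an estimated correlation). Krt23, Prom1 and Krt8 were 15.1-fold, 7.90-fold and 4.49-fold higher. Of 12 oncofetal genes 5 rose and none fell, also adjusted over the list alone (median 0.70; camera adjusted p = 0.00123; adjusted p = 0.781 with an estimated correlation). Afp, alpha-fetoprotein, was 5.41-fold, Ly6d 97.2-fold (59.4-fold with normexp), Cbr3, a carbonyl reductase gene, 15.6-fold and Mest 2.51-fold higher, the last in 1 of its 2 probes. Cbr3 was 8.58-fold higher without PVBL 3, and the call of Mest was lost without PVBL 1 or any 1 sham array (2.16-fold to 2.83-fold). T and NK cell markers fell in 7 of 21 cases and rose in none (9 adjusted over the list alone), with a median of -0.55, or -0.12 with spike-in scaling (camera adjusted p = 0.00647; adjusted p = 0.781 with an estimated correlation). Cd3d, Cd5 (measured on 2 of the 3 PVBL arrays) and Cxcr6 were 1.98-fold, 1.85-fold and 1.68-fold lower and Cd8a at least 1.63-fold lower. The call of Cd5 was lost without PVBL 1 or any 1 sham array (-1.01 to -0.85), that of Cxcr6 without PVBL 1 or sham 2 (-0.73 and -0.74) and that of Cd8a without sham 1 or sham 3.

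Sinusoidal endothelial markers had 10 of 33 members lower and 2 higher (11 and 2 adjusted over the list alone), with Clec4g, Dnase1l3, Ptprb and Oit3 2.81-fold, 2.68-fold, 2.42-fold and 2.36-fold lower. The call of Oit3 was lost without any 1 array but PVBL 3 (-1.31 to -0.999). The list missed the threshold (median -0.47, but -0.045 with spike-in scaling; camera adjusted p = 0.0576) and passed it without PVBL replicate 3 (median -0.60, adjusted p = 2.75e-05) or sham replicate 1 (median -0.47, adjusted p = 0.0304). Of 18 Kupffer cell markers only Marco, a scavenger receptor gene, changed, 5.72-fold higher, also adjusted over the list alone. Their median was -0.42, but above 0 (0.0052) with spike-in scaling (camera adjusted p = 0.457), and without PVBL replicate 3 it was -0.81 and past the threshold (adjusted p = 7.50e-05). Of 31 markers of monocyte-derived macrophages 7 rose and 1 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0576), and the list passed the threshold without PVBL replicate 1, PVBL replicate 2 or sham replicate 3 (medians 0.35, 0.55 and 0.35), while without PVBL replicate 3 the median was below 0 (-0.15, adjusted p = 0.887). S100a11, Ccl2, Ccl9 and Cd63 were 6.20-fold, 4.62-fold, 3.61-fold and 3.30-fold higher. None of 12 neutrophil markers was called, also adjusted over the list alone (median -0.03, above 0 with quantile, median, spike-in and the other percentile scaling, and at 0.065, 0.014 and 0.024 without PVBL 1, sham 1 and sham 2; mean 0.03, camera adjusted p = 0.916). The brightest of them, Csf3r and Elane, differed by -0.30 ± 0.14 and 0.00 ± 0.23, the former above 0 with spike-in scaling and called lower with array weights (-0.32), the latter below 0 with quantile scaling and without PVBL 1, PVBL 2 or sham 3.

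B cell markers (1 of 13 higher, 2 lower), erythroid markers (1 of 12 higher, 4 lower) and pancreatic markers (none of 8 higher, 2 lower) had no called shift (medians -0.40, -0.43 and -0.24, the first and last above 0 and the second at -0.0049 with spike-in scaling; camera adjusted p = 0.325, 0.280 and 0.442), and the counts were the same adjusted over the list alone. The erythroid list passed the threshold without PVBL replicate 2 (median -0.79, adjusted p = 0.0290). Blnk was 3.26-fold higher and Cd22 1.83-fold lower. The erythroid genes Klf1, Car1 and Alas2 were 3.95-fold (2.12-fold with normexp), 3.78-fold and 2.13-fold lower and Car2 2.40-fold higher, the call of Alas2 being lost without sham 3 (-0.99). Ctrl and Ctrb1, of pancreatic proteases, were 1.77-fold and 1.68-fold lower, the call of Ctrl being lost without PVBL 1, PVBL 2, sham 1 or sham 3 (-0.87 to -0.62). All 8 measured adipocyte markers were called, 3 higher and 5 lower, also adjusted over the list alone (median -0.99, or -0.66 with 1 member at its bound; camera adjusted p = 0.550). Cfd and Car3, the latter also a hepatocyte gene, were 6.95-fold (2.92-fold with normexp) and 6.37-fold lower and Lpl and Fabp4 2.77-fold and 2.16-fold higher, and without PVBL 3 Car3 was 3.93-fold lower. Of 17 housekeeping genes 4 rose and 1 fell, also adjusted over the list alone, with a median of -0.04 (above 0 with normexp, quantile, median and spike-in scaling, and at 0.026 without PVBL replicate 3), a mean of 0.10 and a camera adjusted p of 0.491. Tfrc, Ywhaz and Actb were 2.67-fold, 1.81-fold and 1.48-fold higher and Eef1a1 1.46-fold lower. The call of Actb was lost without sham 2 (0.51) and that of Eef1a1 without any 1 sham array (-0.57 to -0.50). Gapdh differed by -0.08 ± 0.14 (adjusted p = 0.695), and its sign turned with normexp, quantile, median and spike-in scaling and without PVBL 3.

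**Figure D3:**
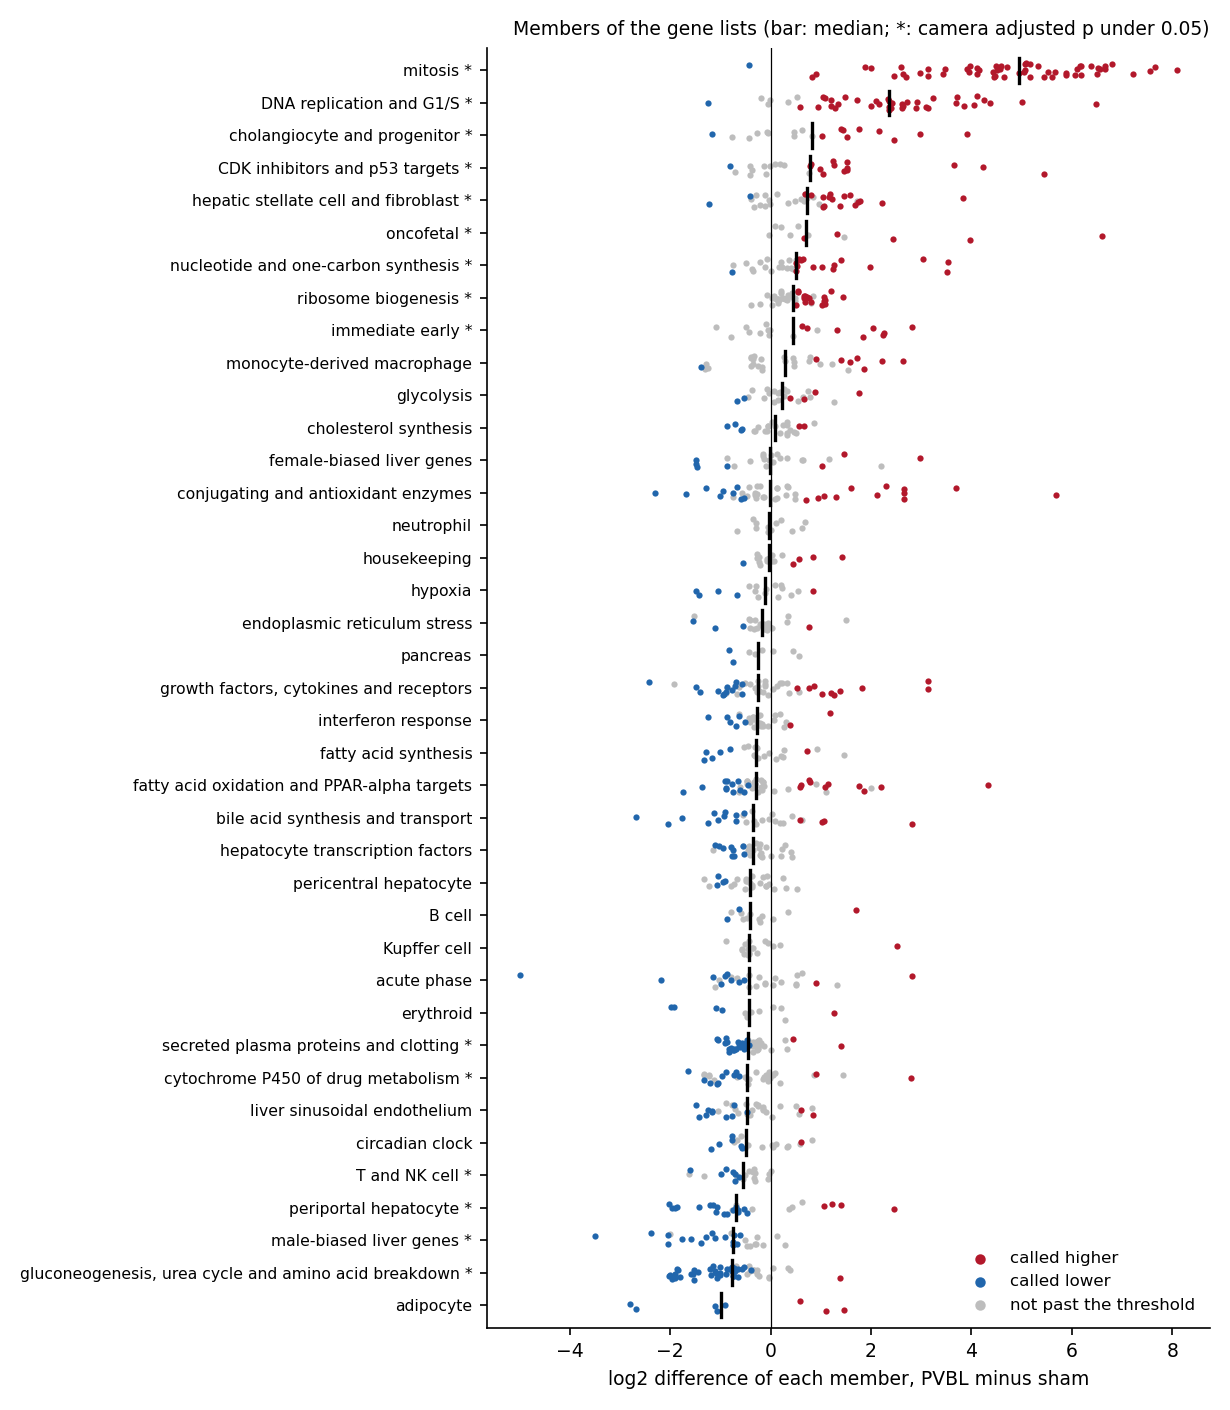
Each point is a tested member of 1 of the 39 gene lists, placed by its log2 difference between PVBL and sham, red where called higher, blue where called lower and grey where it missed the threshold, with the list's median as a black bar and a star at the 15 lists past the threshold in camera. The mitosis list has its median at 4.95 and the gluconeogenesis, urea cycle and amino acid list at -0.77.

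Among genes well above background on all arrays, the largest falls after Hamp2 were in Bmf, a pro-apoptotic gene, 14.3-fold lower, Ppp1r3g, a regulator of glycogen synthesis, 12.2-fold lower, Hsd3b5, the chemokine gene Ccl21a at 8.76-fold, the sulfotransferase genes Sult2a8 and Sult2a7 at 8.65-fold and 7.89-fold, Pax2 at 7.32-fold and Upp2, uridine phosphorylase, at 7.17-fold, beside 1 gene with only a provisional name. Without PVBL 3 Hsd3b5 was 4.64-fold and Sult2a8 4.97-fold lower. With normexp Bmf, Ppp1r3g, Ccl21a and Sult2a7 were 8.09-fold, 7.97-fold, 4.77-fold and 4.71-fold lower. Olfr677, Msmp, Lhx9, Myh2 and Scn4b were well above background on all 3 sham arrays and on no PVBL array. They were at least 4.16-fold, 3.93-fold, 3.89-fold, 3.73-fold and 3.43-fold lower by the scanner's processed signal, and 1.72-fold to 2.15-fold lower with normexp. In all, 140 called genes were above background on all PVBL arrays and no sham array, and 90 the other way round. With an estimated correlation between members, none of the 39 lists passed the threshold (adjusted p from 0.264 to 0.954). The list calls above were thus made only with camera's preset correlation of 0.01. A higher correlation does not account for every loss, since CDK inhibitors and p53 targets had an estimated correlation of -0.024 (camera adjusted p = 0.264). Fry uses no preset correlation but compares no list with other genes. It had 13 lists past its threshold, with mitosis at a fry adjusted p of 7.36e-05.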

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

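The test of probes without a gene name was chosen after the data were examined. The comparison in the report covers named genes alone, and a signal appeared among the probes it left aside. Of 10389 unnamed probes above background, 2728 (26.3%) passed limma's adjusted p threshold of 0.05, 570 higher and 2158 lower in PVBL. Among named genes the share was 32.9%. Of the 10389 probes, 4879 were designed against genomic regions named by their position, and 1345 of these passed, 183 higher and 1162 lower. These counts are from the main scaling alone. For named genes the count of lower genes was 2422 with that scaling, 1559 with median scaling and 171 with spike-in scaling. Whether the excess of falls among unnamed probes holds under another scaling was not tested. The largest rises of such regions were on chromosome 9 from 78107225 to 78118850 (mouse build mm9), where 2 probes had log2 differences of 6.26 ± 0.43 and 5.62 ± 0.38, and on chromosome 17 from 95150800 to 95180650 (4.79 ± 0.17). A region on chromosome 2 from 77715502 to 77719430 rose by 4.10. The largest falls were on chromosome 8 from 49866197 to 49866841 (-3.42 ± 0.51) and on chromosome 4 from 135896689 to 135918414 (-3.22 ± 0.41). What these regions hold was not analysed here.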

How the results depend on the processing

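Spike-in scaling and the fit on PVBL 1, PVBL 2, sham 1 and sham 2 were chosen after the data were examined. Of 167 named genes with a call, 130 kept it whichever array was left out, 21 lost it in 1 to 3 of the 6 such fits and 16 in 4 or more, Met in all 6. No list that was called changed direction in a called result under any alternative run. The same held for named genes in the alternatives with 1 value per gene. Single probes were not part of that count. Of all genes tested, 22 had probes called in opposite directions, a named gene among them. A slide or scan block was not run, because all arrays share 1 slide and 1 scan. Signal over background limits the fold of genes dim in 1 group to a bound. The cause of the changes below was not tested, except that some fits had fewer arrays or more genes. The normexp offset of 50 makes the folds of dim genes smaller, and with spike-in scaling the spread of the spike-in signals enters every gene.

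The count of changed genes was 7819 with array weights (3328 higher, 4491 lower, PVBL 1 weighted 5.51), 2907 with an unmoderated test (1444 lower) and 1655 with spike-in scaling (171 lower). It was 1582 for lower genes without a filter on dim probes and 1559 with median scaling, and 917 genes differed at least 2-fold after normexp. With 1 array left out the count was 2391 to 4782 for changed, 1322 to 2218 for higher and 1069 to 2564 for lower genes. Samples with the same number correlated with r = 0.166, -0.0631 and 0.185 in their deviations from the group means, not every array correlated best with its own number, and the numbers were not taken to pair the samples. With the number as a replicate block 3803 genes changed, and the lists of hepatocyte transcription factors (-0.35), pericentral (-0.40), sinusoidal endothelial (-0.47) and monocyte-derived macrophage markers (0.29) passed the threshold.

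List values here are median log2 differences. With camera's correlation estimated, 0 lists passed. The lost lists were DNA replication (2.35), mitosis (4.95), CDK inhibitors (0.79), immediate early (0.45), P450 (-0.47), male-biased (-0.75), gluconeogenesis (-0.77), nucleotide synthesis (0.50), ribosome biogenesis (0.45), plasma proteins (-0.44), periportal (-0.70), cholangiocyte (0.82), oncofetal (0.70), stellate (0.72) and T and NK cell (-0.55). With fry, immediate early (0.45), P450 (-0.47), male-biased (-0.75) and stellate lists (0.72) were lost, and conjugating enzymes (-0.020) and adipocyte markers (-0.99) gained.

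The immediate early list lost its call with normexp (0.30), quantile (0.47) and median scaling (0.58), probes above background on all arrays (0.22), array weights (0.32) and the 4 arrays alone (0.26). The P450 list lost it with quantile scaling (-0.27), the authors' table (-0.67), no filter (-0.44), a floor (-0.47) and the 4 arrays alone (-0.29). Plasma proteins lost it with quantile scaling (-0.062), and stellate markers with the authors' table (1.06). Rows of that table were chosen on the group difference, so its list values here and below compare chosen members with other chosen genes.

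Glycolysis gained a call with normexp (0.26), quantile scaling (0.45), no filter (0.23) and single probes (0.14). Hepatocyte transcription factors gained one with median scaling (-0.22), the other percentile (-0.32), the authors' table (-0.87), no filter (-0.35), single probes (-0.35) and trended eBayes (-0.35). Pericentral markers gained one with median scaling (-0.27), the other percentile (-0.37), no filter (-0.40), single probes (-0.47), trended eBayes (-0.40) and spike-in scaling, where camera placed them below the other genes at a median of 0.023. Sinusoidal endothelial markers gained one with median scaling (-0.34), the authors' table (-1.03), no filter (-0.47), the mean over probes (-0.47), single probes (-0.47), trended eBayes (-0.47), array weights (-0.64), spike-in scaling (-0.045) and the 4 arrays alone (-0.65). Macrophage markers gained one with the authors' table (1.58) and no filter (0.45), and Kupffer markers with array weights (-0.73) and the 4 arrays alone (-0.75). With single probes, bile acid genes (-0.49) and conjugating enzymes (0.13) gained one.

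With 1 array left out, lists whose call changed ranged as follows. Immediate early genes were at 0.14 to 0.65, P450 at -0.57 to -0.28, pericentral markers at -0.52 to -0.21 and hepatocyte transcription factors at -0.52 to -0.26. Sinusoidal endothelial markers were at -0.60 to -0.32, Kupffer at -0.81 to -0.16, macrophage at -0.15 to 0.55 and erythroid at -0.79 to -0.073. Interferon genes were at -0.37 to -0.20, glycolysis at 0.19 to 0.30 and acute phase at -0.53 to -0.30. The number of lists past the threshold was 15 to 18.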

Other observations

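The tests of the slide row, of spike-in scaling, of the share of hepatocytes and of BMP signalling, and the tests of the lists of iron handling and lipid droplet genes, were chosen only after the result was seen, as were the genes given as examples of the added lists. Genes of homologous recombination and Fanconi anaemia repair, in none of the 39 lists, moved with the replication genes. Of 27 tested, 15 rose and 1 fell, with a median of 1.63, or 1.12 with 5 members at their bound (camera adjusted p = 1.06e-09; adjusted p = 0.119 with an estimated correlation). Fanca was 13.7-fold and Brca2 3.12-fold higher, Fanci and Exo1 at least 17.2-fold and 24.0-fold higher, and Fance fell by 0.85 on the log2 scale.

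Lists of iron handling and lipid droplet genes were drawn up because of genes already seen to change, and were tested without the members of the fixed lists and the BMP targets weighed below. Of the 13 iron handling genes left, 3 fell and 1 rose, with a median of -0.31, but 0.12 with spike-in scaling, and no shift was called (camera adjusted p = 0.190). Tmprss6 and Tfr2, regulators of hepcidin, were among those that fell (-0.62 and -0.77). Of the 11 lipid droplet genes left, 3 fell and 1 rose, with a median of -0.13, but 0.30 with spike-in scaling, and no shift was called (camera adjusted p = 0.709). The lipase inhibitor gene G0s2 was 1.93-fold lower.

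The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4475 changed genes, 2053 higher, 2422 lower and 1556 at least 2-fold, and the highest of the other splits gave 0 for each, so 1 of 10 splits reached each real count. For lists past the threshold the real split gave 15, the highest other 24, and 7 of 10 splits, the real one included, gave at least as many. Each other split sets 2 PVBL arrays and 1 sham array against the reverse and so keeps part of the difference, and its counts are not those of samples without a difference. Slide row followed the surgery. Before scaling, 8 spike-in probes differed between the rows by at most 0.0363 on the log2 scale (0.342 with 2 SE added), so they showed no 2-fold difference in brightness. Genes were called after each array's 75th percentile was subtracted, which removes an even difference in brightness, so this test cannot decide about the calls. Relative to that percentile the spike-in median was 5.02, 5.68 and 5.55 on PVBL 1 to 3 and 5.61, 5.57 and 6.36 on sham 1 to 3. Effects of the row on the calls stay open.

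The falls of hepatocyte genes were weighed against the scaling and the cell mix. The per-array median of 168 genes, the tested members of the 5 hepatocyte lists with a called fall and so chosen for it, differed between PVBL and sham by -0.58 ± 0.11 (SE, n = 3 per group) with the 75th percentile and by -0.157 ± 0.327 with spike-in scaling, where 17 rather than 88 were called lower. Whether these transcripts fell per amount of RNA thus cannot be told apart from the scaling, because the spike-in spread is wide. A lower share of hepatocytes alone would raise the markers of other cells alike, but stellate markers rose over endothelial ones by 1.21 ± 0.10 and T and NK markers were at -0.62. The gap does not measure cell shares, since stellate genes can change within the cells. The stellate members Lrat and Fn1, named after their values were seen, fell (-1.23 and -0.41). Markers of other cells thus did not rise alike, but a lower share of hepatocytes stays open, as does a change within stellate cells or in the hepatocytes themselves.

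Hypotheses were tested for 3 other changes. The rise of Gsta1, Gstm3, Srxn1 and Nqo1 may reflect activity of the transcription factor NRF2: of 20 known targets outside the fixed lists 8 rose and 1 fell, with a median of 0.362 (camera adjusted p = 0.00415; adjusted p = 0.194 with an estimated correlation), Ptgr1 being 12.3-fold higher and Cat, catalase, 1.84-fold lower. For weaker growth hormone signalling behind the fall of male-biased liver genes, 0 of Socs2 and Cish were called lower (-0.40 and -0.81, adjusted p = 0.339 and 0.364), which leaves it open. The fall of Hamp and Hamp2 could go with weaker BMP and SMAD signalling, since 3 of 4 other targets, Smad6, Smad7 and Atoh8, fell (-0.61, -0.87 and -1.06), while Id1 differed by 0.82 (adjusted p = 0.0711). The falls of these targets are relative to the bulk of the genes, and with spike-in scaling 171 genes in all were called lower.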
